A study of Mus musculus with 3 samples.

How the data were processed

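KIT-positive mouse bone marrow cells were profiled by RNA-seq in 3 libraries, 1 each for the control, JAK2-617F and MPL515L groups, which were taken from the sample titles. Per the labels' protocols, total RNA was extracted with on-column DNase treatment and made into stranded, poly(A)-selected libraries, which were read as pairs. The values used here are read counts per gene as deposited by the authors. Per the submitters' processing notes, reads were checked with FastQC, aligned with HISAT2 to the mm10 build and counted with featureCounts. The versions, the strand setting and the handling of pairs, of reads on more than 1 gene and of multiply aligned reads are not given in the sources used here.

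The deposited count table held 27179 Entrez gene IDs with no count below 1. A value of 1 can therefore stand for 0 or for 1, or for 0 if 1 was added throughout, and 9251 IDs were at 1 in all 3 libraries. Genes at 1 in a library were treated as undetected there: ratios against them are given as bounds, computed with a floor of 3 counts per library. Symbols came from a RefSeq table of GRCm38.p6, which named 25275 IDs, and GENCODE release M21 named 18 more, so that 93.1% had a symbol. The 1886 IDs without a symbol stayed in library totals and in counts of genes but were not named. Coordinates are those of the RefSeq table on GRCm38, the assembly of mm10.

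Library totals were 44623818 counts for the control, 16725185 for JAK2-617F and 36348281 for MPL515L. The 10 most abundant genes took 4.84%, 4.85% and 4.80% of them. A floor of 3 counts is 0.0672, 0.179 and 0.0825 CPM (counts scaled to library size) in the same order. Counts were scaled with TMM factors from edgeR (version 4.0.16, R 4.3.3), which were 0.990 for the control, 1.01 for JAK2-617F and 1.00 for MPL515L, and expressed as CPM. A log2 ratio was taken after adding 1 CPM to both values, which understates the ratio of low genes. Fold values are ratios of CPM with nothing added. Genes with a mean of at least 1 CPM over the 3 libraries were described, and a gene was counted as higher or lower at a log2 ratio of at least 1 in size.

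With 1 library per group there is no test of any gene, no p-value and no replicate spread, and no fitted model across genes. Each fold has an exact conditional binomial 95% interval from the 2 counts. It covers counting error only, since reads without molecular identifiers are not independent molecules. If both mates of a pair were counted in the control, its intervals are too narrow, and they were computed again with the control count halved. In the JAK2-617F library, the shallowest, the intervals of low genes are the widest.

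Gene lists were fixed before the data were examined. Pathway lists covered AP-1 and immediate early genes, dual specificity phosphatases, ERK feedback genes, MAP kinases, STAT5 targets, JAK-STAT components and receptors, the interferon response, inflammatory cytokines and NF-kB genes, p53 targets, the BCL2 family, G2/M, G1/S, glycolysis and hypoxia, cholesterol synthesis, the integrated stress and unfolded protein response, oxidative stress, and heme synthesis and iron. Cell type lists covered erythroid cells, megakaryocytes, neutrophil primary granules, neutrophil maturation, monocytes and macrophages, mast cells and basophils, eosinophils, dendritic cells with MHC class II, stem and progenitor cells, B cells, T and NK cells, and stromal and endothelial cells. Reference housekeeping genes and mitochondrially encoded genes were technical lists, and of the mitochondrial list 0 members were measured. Each list of the other 30 was described by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of the same size. These were drawn from all named genes with a mean of at least 1 CPM. They were matched on mean expression over the 3 libraries in 20 bins. The percentile describes these libraries and is no inference to the conditions.

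The genes named were set by rule before the data were examined: for each comparison the 10 highest and 10 lowest log2 ratios among genes with a mean of at least 10 CPM in the libraries compared, leaving out predicted genes with Gm or Rik symbols and IDs without a symbol, up to 4 members of each described list with the largest log2 ratios, 5 genes per side for both comparisons against the control jointly, and Jak2, Mpl, Dusp1 and Fos. A second set of 10 per side, from genes without overlap or shared sequence, was added after seeing the data.

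That restriction followed from the counts themselves. Exon overlap on either strand was found with bedtools (version 2.31.1) in GENCODE release M21, an ID without a symbol next to a gene in the table's order was taken as an unnamed neighbour, and shared sequence was measured as the percent of a gene's 50-base words found in the transcripts of another gene. Of 12902 genes past the floor, 6398 had a symbol in GENCODE, no overlap and no unnamed neighbour, and 5909 of these shared under 10% of their words. Genes whose symbol is absent from GENCODE have no known overlap status and were set with the overlapping genes. The kit keeps strand, but counting by strand is not stated, so overlaps on the opposite strand were treated like those on the same strand.

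The ratio, interval and list steps were tested on simulated counts drawn at the real depths, with 200 genes changed by known folds among 12902. In the JAK2-617F comparison with the control, 0 unchanged genes reached 2-fold, and 0% of genes changed 1.5-fold and 100% of those changed 3-fold were counted. For MPL515L against the control 98% of genes changed 3-fold were counted, and for JAK2-617F against MPL515L 96%. All genes changed 4-fold or 8-fold were counted. Intervals covered the true ratio for 95.2%, 94.9% and 95.7% of 646 genes in the 3 comparisons. These simulated counts held counting noise only, with no spread between cells or preparations and no difference in counting. They therefore do not measure how often unchanged genes differ by 2-fold between single real libraries. The alternatives were scaling by library total or by DESeq2 (version 1.42.0) median-of-ratios factors, 0.1 or 5 CPM added, no floor or a floor of 10 CPM, a 4-fold threshold, and leaving out Gm and Rik genes. Those added after seeing the data were the restricted gene sets and 1 subtracted from every count. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps, and matplotlib 3.10.9 for the plots.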

Results

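Messenger RNA was sequenced from KIT-positive mouse bone marrow cells, a fraction enriched for haematopoietic progenitors and for the mast cell lineage, which keeps the KIT receptor. There were 3 libraries, 1 per group. The first was labelled control, the second came from cells given the JAK2-617F oncogene, a mutant of the kinase that signals from the erythropoietin and thrombopoietin receptors, and the third from cells given the MPL515L oncogene, a mutant of the thrombopoietin receptor itself. Both oncogenes drive myeloproliferative neoplasms. The description of the control carries a mark of 72 h that the other libraries lack and the labels do not explain, so a difference in time may underlie any ratio against the control. The control library held 44623818 counts, the JAK2-617F library 16725185 and the MPL515L library 36348281, over 27179 gene IDs. A mean of at least 1 CPM (a count scaled to library size) was reached by 12902 genes. No group had a replicate, so every difference below is between single libraries and has no replicate check, and the intervals cover counting error only.

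The transduced genes were read first, since they check the labels. Jak2 (Entrez 16452, chromosome 19, 29251803 to 29313095, mm10) stood at 810 CPM in the JAK2-617F library, 227 CPM in the MPL515L library and 101 CPM in the control. The JAK2-617F library was thus 8.003-fold above the control (95% counting interval 7.74 to 8.28) and 3.57-fold above the MPL515L library (3.48 to 3.67), while the MPL515L library was 2.24-fold above the control (2.16 to 2.32). Jak2 has an unnamed neighbouring ID in the table, which bears on its ratios against the control, as described below. Mpl (Entrez 17480, chromosome 4, 118442412 to 118457688) stood at 4552 CPM in the MPL515L library, 23.5 CPM in the control and 11.7 CPM in the JAK2-617F library. The MPL515L library was 194-fold above the control (182 to 206), and the JAK2-617F library was 2.004-fold below it (1.72 to 2.35). Each oncogene was therefore highest in the library labelled with its name. The counts do not separate transduced from endogenous transcripts, and the labels state neither whether the transduced sequences were mouse or human, which bears on how many of their reads count for the mouse genes, nor whether the control carried an empty vector.

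Dusp1, the gene named in the series title, encodes a phosphatase that inactivates MAP kinases and is itself induced as an immediate early gene. It lies on chromosome 17 (Entrez 19252, 26505591 to 26508472). Dusp1 stood at 24.5 CPM in the JAK2-617F library, 59.1 CPM in the MPL515L library and 2.83 CPM in the control. This was 8.68-fold above the control for JAK2-617F (7.09 to 10.7) and 20.9-fold for MPL515L (17.4 to 25.2), from 413, 2157 and 125 counts. Dusp1 has an annotated overlap on the opposite strand and an unnamed neighbouring ID in the table. With the control count halved, for the reason given below, the intervals were 6.64 to 11.5 and 16.2 to 27.3. Fos (Entrez 14281, chromosome 12, 85473890 to 85477274), an AP-1 subunit with no overlapping gene, stood at 80.5, 285 and 10.6 CPM in the same order. It was 7.57-fold above the control for JAK2-617F (6.81 to 8.43) and 26.8-fold for MPL515L (24.4 to 29.5). Between the transduced libraries, JAK2-617F was 2.41-fold below MPL515L for Dusp1 (2.17 to 2.68) and 3.54-fold below it for Fos (3.35 to 3.75).

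**Figure D1:**
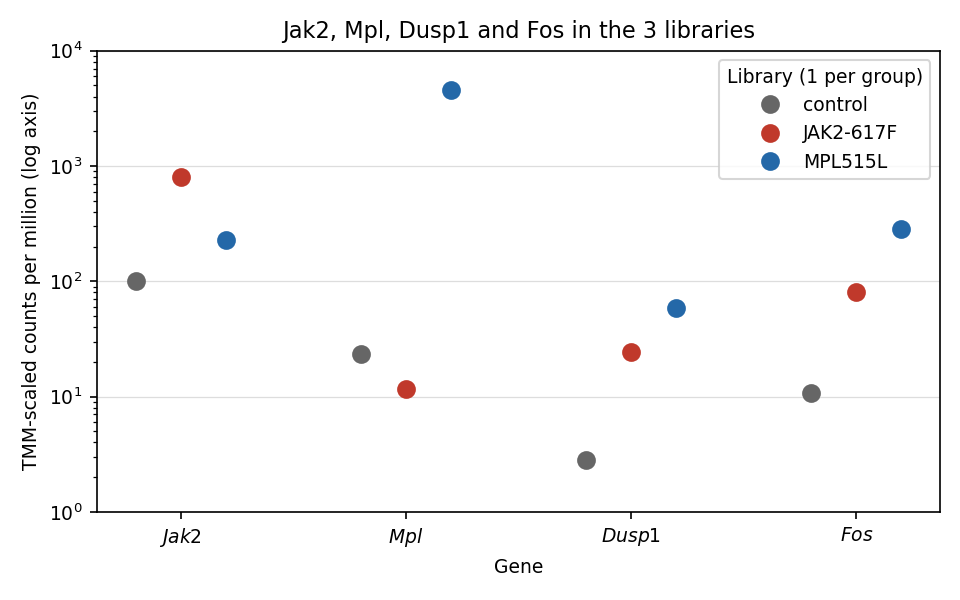
TMM-scaled CPM of Jak2, Mpl, Dusp1 and Fos (x axis) on a log axis, with 1 point for each library and no error bars, since each group is 1 library. Jak2 is highest in the JAK2-617F library at 810 CPM, Mpl in the MPL515L library at 4552 CPM, and Dusp1 and Fos are lowest in the control at 2.83 and 10.6 CPM.

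The control column was distributed differently from the other columns, which bears on every comparison against it. Among counts from 2 to 19, 75.6% were even in the control, against 54.8% in the JAK2-617F library and 55.4% in the MPL515L library. IDs without a symbol took 3.42% of the control's counts, 0.290% of the JAK2-617F counts and 0.367% of the MPL515L counts. Tmsb4x, an abundant actin-binding peptide gene beside such an ID, had 70844 counts in the control, 3 in the JAK2-617F library and 14 in the MPL515L library. Each comparison against the control is therefore also given for 5909 genes with no annotated exon overlap, no unnamed neighbour and under 10% of sequence shared with other genes, a restriction chosen after seeing the data.

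Comparison of the JAK2-617F library with the control asks which transcripts differ in cells carrying mutant JAK2. The list medians of immediate early, inflammatory cytokine, mast cell and MHC class II genes were higher in the JAK2-617F library, and those of neutrophil maturation and eosinophil genes were lower. Among mast cell genes the chymase Cma1 was 59.4-fold higher (45.6 to 78.6) and the tryptase Tpsb2 45.0-fold higher (33.4 to 62.0), and among cytokines Lif was 50.3-fold higher (38.6 to 66.7). Retnlg, a neutrophil resistin-like protein, was 81.4-fold lower (50.1 to 143), and the gelatinase Mmp9 was 27.9-fold lower (22.6 to 34.8). In all, 484 genes were at least 2-fold higher and 1158 at least 2-fold lower, so that 29.5% of the differences were higher. Among the 5909 genes free of overlap and shared sequence, 241 were higher and 138 lower, and 63.6% were higher.

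The AP-1 and immediate early list had a median log2 ratio of 0.84 in the JAK2-617F library against the control, with 10 of its 24 measured members at least 2-fold higher and 1 lower. Egr1, a transcription factor induced within minutes of growth factor signalling, was 22.9-fold higher (20.7 to 25.4). Fosb was 194-fold higher (74.8 to 716) from 4 control counts, and Egr3 14.0-fold higher (9.74 to 20.8). The lower member was Fosl1, which has an opposite-strand overlap. Of 10 dual specificity phosphatases, Dusp1 alone was at least 2-fold higher, and the list median was 0.53. Inflammatory cytokine and NF-kB genes had a median of 0.95, with 12 of 27 higher and 0 lower. Besides Lif, the cytokine gene Osm was 10.1-fold higher (9.25 to 10.97), Il6 9.01-fold (7.19 to 11.4) and the chemokine gene Ccl3 6.76-fold (5.96 to 7.69). Il6 and Ccl3 are also members of the mast cell list, and on members in no other list the inflammatory median was 0.67. The interferon response list had a median of 0.57, with 7 of 29 higher. Its member with the largest ratio, the GTPase gene Iigp1, sat at the table's minimum in the control and was at least 82.3-fold higher. These lists lay at percentiles of 99.92 to 100 among 10000 random lists of matched expression.

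Mast cell and basophil genes had a median log2 ratio of 1.87 in the JAK2-617F library, or 1.81 with members at the table's minimum set to a floor of 3 counts. At least 2-fold higher were 17 of 23 members, and none was lower. The protease gene Mcpt2 sat at the minimum in the control and was at least 244-fold higher, and Tph1, which makes serotonin in mast cells, was 19.6-fold higher (16.8 to 23.0). Dendritic cell and MHC class II genes had a median of 1.53, with 11 of 19 higher and 0 lower. Examples were Clec10a (log2 ratio 2.44), the MHC class II chain H2-Aa (2.04) and its invariant chain Cd74 (2.22). Monocyte and macrophage genes went both ways, with 12 of 30 higher, 4 lower and a median of 0.64. The elastase Mmp12 was 10.2-fold higher (9.28 to 11.3), whereas the complement genes C1qb, C1qa and C1qc were 11.6-fold (9.30 to 14.7), 10.3-fold (7.38 to 14.9) and 5.66-fold (4.60 to 7.05) lower. Neutrophil maturation genes had a median of -1.29, with 14 of 25 lower and 3 higher. Besides Retnlg and Mmp9, the antimicrobial peptide gene Camp was 12.8-fold lower (11.8 to 14.0). The higher members, Stfa1, Stfa2 and Stfa3, belong to the stefin family, with 22.5% of Stfa1 sequence shared. The neutrophil primary granule list, which marks an earlier stage, had a median of -0.35, with 2 of 12 lower. Its median was 0.07 on the 6 members without overlap or shared sequence. Eosinophil genes had a median of -1.82, with 6 of 8 lower, among them the peroxidase Epx (7.65-fold, 6.74 to 8.72).

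Among other lineages in the JAK2-617F library, megakaryocyte and platelet genes had a median log2 ratio of -0.07 against the control, with 3 of 28 higher and 2 lower. Erythroid genes had a median of -0.45, with 5 of 21 lower and 2 higher. The haemoglobin genes of this list are near copies of each other, and Zfpm1, the GATA1 cofactor, was 2.53-fold lower (2.26 to 2.83). Stem and progenitor genes had a median of -0.38, with 3 of 27 lower and 2 higher. Hlf, a stem cell transcription factor, was 2.90-fold lower (2.41 to 3.52), while Procr was 7.45-fold higher (4.90 to 11.6) and Ly6a, a member of a family with shared sequence, 7.05-fold higher (6.63 to 7.496). STAT5 target genes had a median of 0.05, with 2 of 17 higher and 2 lower, and of -0.21 on the 8 members without overlap or shared sequence. The feedback inhibitor Cish, which overlaps a gene on the opposite strand, was 2.95-fold higher (2.71 to 3.22). JAK-STAT components and receptors had a median of 0.22, with 5 of 24 higher, among them Jak2, Il6st and Csf2rb2.

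By the fixed rule of size, the 10 highest genes of the JAK2-617F library against the control were Mir682, Cma1, Lif, Tpsb2, Egr1, Tph1, H3f3c, Akr1c18, Mmp13 and Tpsg1. Mir682 and H3f3c share 100% and 73.8% of their sequence with other genes. The 10 lowest were Tmsb4x, Mir5121, H3f3b, Lrch4, Tsix, Mir3076, Sdhd, Rsc1a1, Ubc and Ugt1a2, and each of these has an overlapping or unnamed neighbouring gene. In the restricted set the lowest were Retnlg, Mmp9, Camp, Mroh2a, Mmp25, C1qa, Epx, Cd177, C1qc and Lipg. The other genes named for this comparison that have an overlap, an unnamed neighbour or shared sequence are Jak2, Dusp1, Cd74, C1qb, Mmp12, Ly6a, Csf2rb2 and Tpsg1.

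Comparison of the MPL515L library with the control asks the same of the mutant thrombopoietin receptor. The list medians of megakaryocyte, mast cell, MHC class II, interferon, immediate early and inflammatory genes were higher in the MPL515L library, and those of both neutrophil lists and of eosinophil genes were lower. After Mpl, the genes with the highest log2 ratios included Tpsb2, 230-fold higher (172 to 314), and the serotonin transporter Slc6a4, 222-fold higher (157 to 325). The platelet lipoxygenase Alox12 was 159-fold higher (112 to 235). Lipg, an endothelial-type lipase gene, was 103-fold lower (76.9 to 142), Retnlg 202-fold lower (120 to 370) and Mmp9 83.2-fold lower (65.1 to 108). In all, 1185 genes were at least 2-fold higher and 1188 lower, so that 49.9% were higher. Among the 5909 genes free of overlap and shared sequence, 640 were higher and 148 lower, and 81.2% were higher.

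Megakaryocyte and platelet genes had a median log2 ratio of 2.30 in the MPL515L library against the control, and 23 of 28 were at least 2-fold higher with none lower. The median was 2.60 on the 20 members without overlap or shared sequence. The platelet chemokine Ppbp was 19.2-fold higher (18.2 to 20.3) and the collagen receptor Gp6 48.0-fold higher (32.0 to 75.2). Clec1b, the platelet podoplanin receptor, was 63.9-fold higher (47.9 to 87.2) and overlaps a gene on its strand. The list includes Mpl itself. Erythroid genes had a median of 0.67, with 8 of 21 higher, among them the spectrin gene Sptb (4.21-fold, 3.77 to 4.71) and the erythropoietin receptor gene Epor (3.27-fold, 2.70 to 3.99), and 1 lower. Mast cell and basophil genes had a median of 1.83, with 17 of 23 higher and 0 lower. Cma1 was 131-fold higher (101 to 173), and the proteases Mcpt2 and Mcpt4, at the minimum in the control, were at least 1259-fold and 771-fold higher. Stem and progenitor genes had a median of 0.15, with 6 of 27 higher and 3 lower. Slamf1 was 11.9-fold higher (9.86 to 14.5) and Esam 5.02-fold higher (4.21 to 6.01), whereas Hlf was 5.15-fold lower (4.35 to 6.15).

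Dendritic cell and MHC class II genes had a median log2 ratio of 2.31 in the MPL515L library, with 17 of 19 higher and none lower. H2-Aa was 12.97-fold higher (12.2 to 13.8), and the chemokine gene Ccl22 35.2-fold higher (23.1 to 56.6). Monocyte and macrophage genes had a median of 1.42, with 22 of 30 higher and 2 lower. Mmp12 was 13.3-fold higher (12.1 to 14.6), and the fractalkine receptor Cx3cr1 12.8-fold higher (11.3 to 14.6). Interferon response genes had a median of 1.73, with 19 of 29 higher and none lower, led by the antiviral genes Oasl2 (15.6-fold, 12.8 to 19.3) and Mx1 (23.8-fold, 16.7 to 35.0). Inflammatory cytokine and NF-kB genes had a median of 1.67, with 15 of 27 higher, among them Osm (12.6-fold, 11.7 to 13.7) and the prostaglandin synthase Ptgs2 (15.2-fold, 12.6 to 18.5). On members in no other list the inflammatory median was 0.79. AP-1 and immediate early genes had a median of 1.70, with 17 of 24 higher and 1 lower. Egr1 was 52.7-fold higher (47.7 to 58.3) and Atf3 9.53-fold higher (8.55 to 10.7). Of the 10 dual specificity phosphatases, 8 were at least 2-fold higher and 0 lower, with a median of 1.36. On the 5 of them without overlap or shared sequence, the median was 1.04 and 3 were higher. Besides Dusp1, the largest ratios were those of Dusp3 (3.15-fold, 2.98 to 3.33), Dusp10 (3.74-fold, 3.002 to 4.70) and Dusp4 (3.16-fold, 2.69 to 3.72). Each of these lists lay at percentile 99.99 or 100 among the random lists.

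Neutrophil maturation genes had a median log2 ratio of -1.99 in the MPL515L library against the control, with 18 of 25 lower and 0 higher. Camp was 53.7-fold lower (47.7 to 60.7) and the surface glycoprotein Cd177 35.0-fold lower (30.8 to 40.1). Primary granule genes had a median of -1.18, with 7 of 12 lower, including the elastase Elane (4.50-fold, 4.43 to 4.56). On the 6 primary granule members without overlap or shared sequence the median was -0.61, with 2 lower. Eosinophil genes had a median of -1.51, with 6 of 8 lower and Alox15 higher (log2 ratio 2.23). STAT5 target genes had a median of 0.22, with 1 of 17 higher and 1 lower, and of -0.01 on the 8 members without overlap or shared sequence. JAK-STAT components and receptors had a median of 0.48, with 8 of 24 higher, Mpl among them, and of 1.46 on the 7 members without overlap or shared sequence. The cell cycle lists were lower by less than 2-fold, with medians of -0.26 for G2/M and mitosis and -0.38 for G1/S and DNA replication, at percentiles 0.310 and 0.020. Against the same control the JAK2-617F library gave 0.08 and -0.07 for these lists.

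The 10 highest genes of the MPL515L library against the control by the fixed rule were Mpl, Tpsb2, Slc6a4, Mcpt2, Cma1, Alox12, Mcpt4, Egr1, Mir682 and Clec1b. The 10 lowest were Tmsb4x, Mir5121, Lrch4, H3f3b, Tsix, Mir3076, Sdhd, Rpl39, Ugt1a5 and Ugt1a10, each with an overlapping or unnamed neighbouring gene. In the restricted set the lowest were Lipg, Retnlg, Mmp9, Camp, Cd177, Ngp, Chil1, Mroh2a, Itgb2l and Mmp25, most of which are products of maturing neutrophils. Of the other genes named for this comparison, Jak2, Slamf1, Sptb, Mmp12, Cx3cr1, Dusp1, Dusp3, Dusp4 and Elane have an overlap, an unnamed neighbour or shared sequence.

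**Figure D2:**
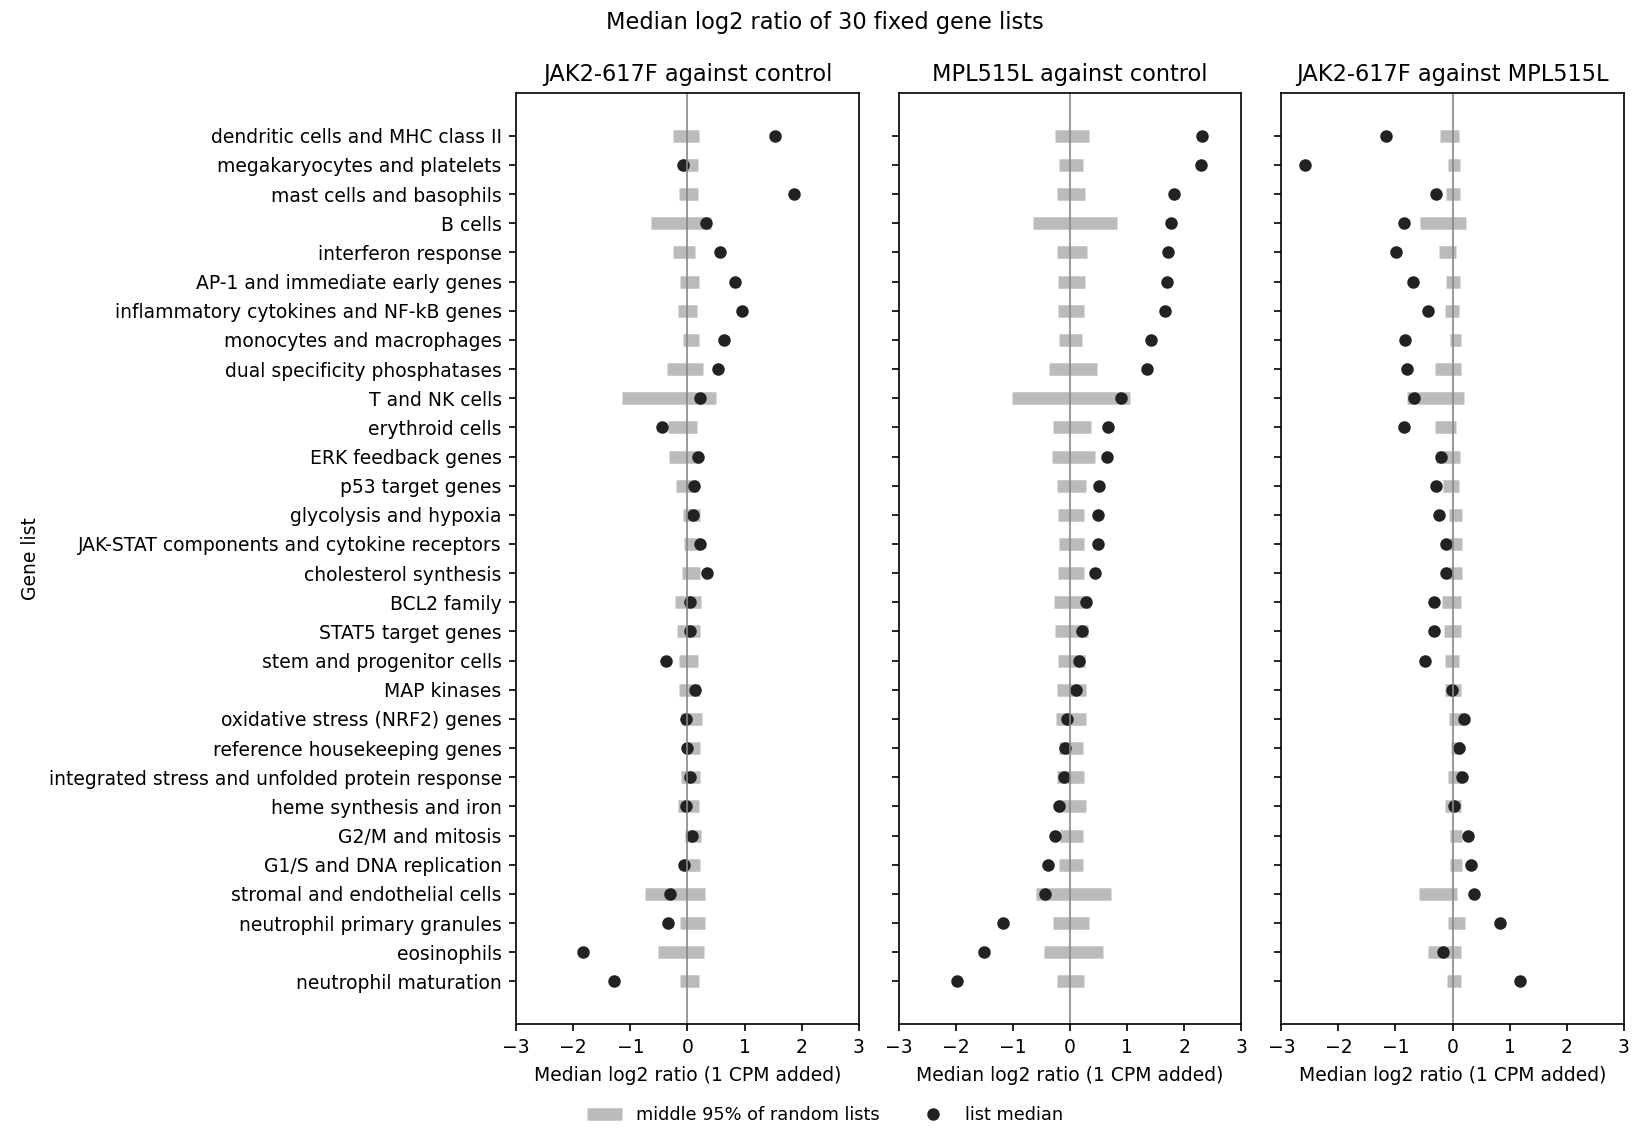
Median log2 ratio (x axis, 1 CPM added) of each of 30 fixed gene lists (y axis) in the 3 comparisons, where a point is the list median and a grey bar the middle 95% of medians of 10000 random lists of matched expression. The megakaryocyte list stands at -0.07, 2.30 and -2.58 in the 3 panels, and the neutrophil maturation list at -1.29, -1.99 and 1.18.

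Comparison of the JAK2-617F library with the MPL515L library sets the oncogenes side by side. It uses the control column only in the expression floor, the scaling factors and the expression matching of the random lists. The list median of megakaryocyte genes was far lower in the JAK2-617F library than in the MPL515L library. Those of interferon, MHC class II, macrophage, erythroid and immediate early genes were lower as well, with many members within 2-fold, and those of both neutrophil lists were higher. At least 2-fold higher were 85 genes and lower were 570, so that 12.98% of the differences were higher. Among the genes free of overlap and shared sequence, 54 were higher and 320 lower. After Mpl, the lowest genes were Slc6a4 (17.0-fold lower, 14.5 to 20.1), Alox12 (17.6-fold, 14.5 to 21.5), the platelet tubulin Tubb1 (30.2-fold, 17.9 to 55.4), Plxna4, Syt13, Clec1b, Fhl1, Nrgn and the von Willebrand receptor subunit Gp9 (12.1-fold, 9.61 to 15.3). The highest were Lipg (21.3-fold higher, 15.6 to 29.7), Stfa1, the chemokine gene Ccl24 (8.32-fold, 6.52 to 10.7), Cstdc5, Cd177 (4.98-fold, 4.26 to 5.83), Olfml2b, the granzyme gene Gzmb (3.92-fold, 3.71 to 4.15), Ltf, Camp and Tph1 (3.73-fold, 3.41 to 4.07). Stfa1 and Cstdc5 belong to the stefin family, with 22.5% of Stfa1 sequence shared and no such value for Cstdc5. Ltf, Plxna4 and Clec1b have an overlap or an unnamed neighbour.

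Of 28 megakaryocyte and platelet genes, 24 were at least 2-fold lower in the JAK2-617F library than in the MPL515L library and 0 higher, with a median log2 ratio of -2.58. Erythroid genes had a median of -0.84, with 7 of 21 lower, among them the erythroid and megakaryocytic factor Gata1 (3.07-fold, 2.70 to 3.51). Interferon response genes had a median of -0.99, with 14 of 29 lower, such as Mx1 (6.73-fold, 4.94 to 9.40), and Iigp1 higher (6.18-fold, 4.12 to 9.49). Dendritic cell and MHC class II genes had a median of -1.17, with 11 of 19 lower and 1 higher, and monocyte and macrophage genes a median of -0.83, with 11 of 30 lower, including the lipoprotein gene Apoe (7.37-fold, 6.76 to 8.04). AP-1 and immediate early genes had a median of -0.70, with 6 of 24 lower, and dual specificity phosphatases a median of -0.81, with 3 of 10 lower. On the 5 phosphatases without overlap or shared sequence the median was -0.45. Inflammatory cytokine and NF-kB genes had a median of -0.43, with 1 of 27 lower (Ptgs2) and 1 higher (Lif, 2.98-fold, 2.72 to 3.27). Mast cell and basophil genes were split, with 4 of 23 lower, 3 higher and a median of -0.30. Mcpt4 was 8.09-fold lower (6.66 to 9.90) and Tpsb2 5.11-fold lower (4.75 to 5.50), whereas Gzmb and Tph1 were higher.

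Neutrophil maturation genes had a median log2 ratio of 1.18 in the JAK2-617F library against the MPL515L library, with 14 of 25 at least 2-fold higher and none lower, and primary granule genes a median of 0.82, with 3 of 12 higher. Stem and progenitor genes had a median of -0.48, with 4 of 27 lower, including Slamf1 (12.7-fold, 9.40 to 17.7), and 2 higher, including Prom1 (3.24-fold, 2.94 to 3.57). STAT5 target genes had a median of -0.33, with 2 of 17 higher, of which Cish was 2.61-fold higher (2.39 to 2.85), and 1 lower. Their mean was -0.0070, and the median on members in no other list was -0.0050. JAK-STAT components and receptors had a median of -0.11, with 1 of 24 higher (Jak2) and 2 lower (Mpl and Epor), and of -0.44 on the 7 members without overlap or shared sequence. Eosinophil genes had a median of -0.16, with 1 of 8 lower. The G2/M and G1/S lists had medians of 0.28 and 0.33, with no member at 2-fold, at percentiles 99.99 and 100.

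**Figure D3:**
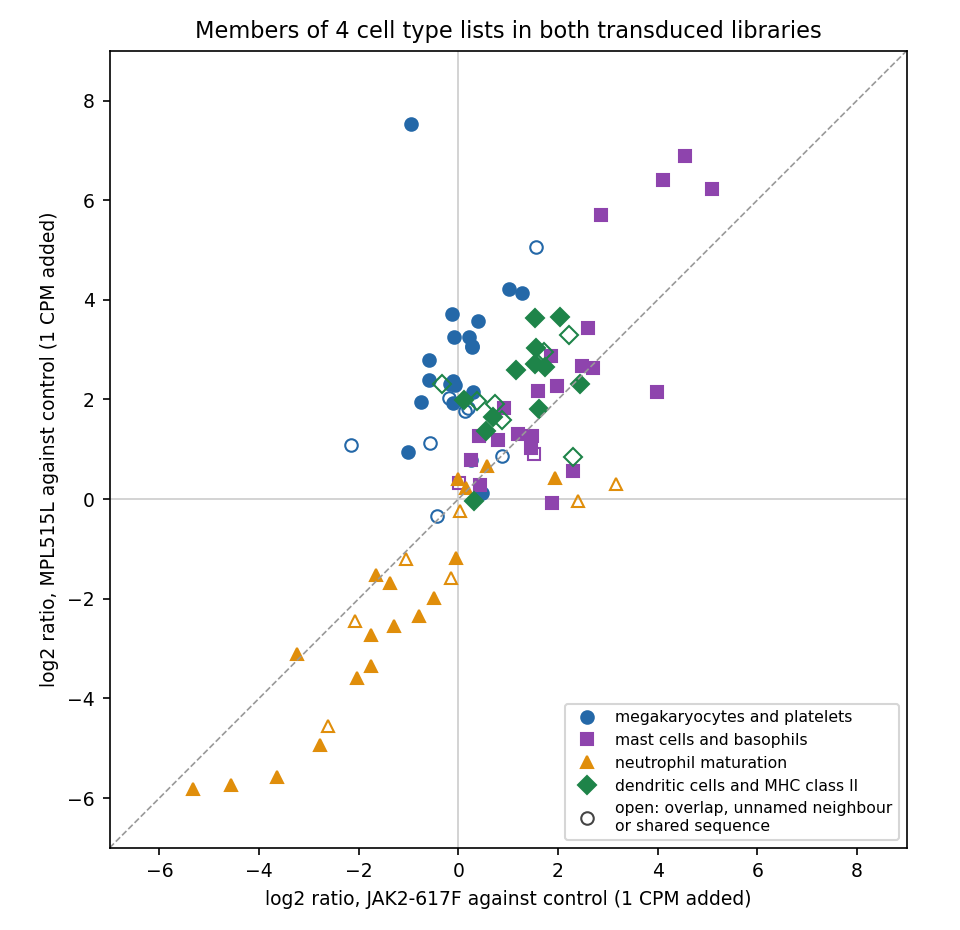
Log2 ratios against the control (1 CPM added) of the measured members of 4 cell type lists, with JAK2-617F on the x axis and MPL515L on the y axis, where each symbol is a gene, open symbols mark genes with an overlap, an unnamed neighbour or shared sequence, and the dashed line marks equal ratios. Mast cell genes lie in the upper right (list medians 1.87 and 1.83), neutrophil maturation genes mostly in the lower left (-1.29 and -1.99), and megakaryocyte genes near 0 on the x axis and high on the y axis (-0.07 and 2.30).

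The comparisons against the control overlapped. At least 2-fold higher in both transduced libraries were 413 genes, where independent lists of the same sizes would share 44.5, and 1008 genes were lower in both, where 107 would be shared. Among genes free of overlap and shared sequence, 214 were higher in both (26.1 for independent lists) and 76 lower in both (3.46). Libraries simulated without any change shared 0 genes in either direction. With the control's counts divided at random into 2 separate parts, 1 for each comparison, 405 and 1000 genes were shared, or 206 and 73 in the restricted set. The covariance of the log2 ratios was 1.35 over all genes and 0.333 in the restricted set, against 0.00298 in the simulation. The simulation holds counting noise only, and both parts of the control come from 1 library with the same cells and counting. Neither can therefore separate out the shared control, and part or all of the excess may come from it. Of the 1008 genes lower in both, 908 have an overlap, an unnamed neighbour, no symbol or a symbol absent from GENCODE. The same holds for 6504 of all 12902 genes. By the fixed rule the genes highest in both were Cma1, Mir682, Tpsb2, Egr1 and H3f3c, and those lowest in both were Tmsb4x, Mir5121, Lrch4, H3f3b and Tsix. In the restricted set they were Cma1, Tpsb2, Egr1, Lif and Osm on the higher side and Retnlg, Mmp9, Camp, Mroh2a and Mmp25 on the lower side.

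Reference housekeeping genes had medians of -0.0047 in the JAK2-617F library and -0.09 in the MPL515L library against the control, with 2 of 27 at least 2-fold lower in each. On the 11 members without overlap or shared sequence the medians were 0.23 and 0.24. The lower genes were Ubc (log2 ratios -6.13 and -5.89) and Ppia (-1.40 and -1.63), both with shared sequence. Between the transduced libraries the housekeeping median was 0.11 and none of the 27 differed by 2-fold. The median log2 ratio of all genes past the floor was -0.0047, -0.0083 and -0.0031 in the 3 comparisons.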

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

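In the tests below, those of reads on more than 1 gene, of depth, of lower expression and of the neutrophil share were chosen only after the results were seen. Those of another counting of the control were written down before their values were seen, but use a gene restriction chosen after seeing the counts. The heat shock test was set down before its result was seen.

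The JAK2-617F and MPL515L libraries lay on opposite sides of the control by at least 2-fold each for 5 genes past the floor, 3 of them with a mean of at least 10 CPM, and in no case was the difference between the effects tested. Adcy6, an adenylyl cyclase gene, had log2 ratios of -1.50 for JAK2-617F and 1.07 for MPL515L. Gp1bb, a subunit of the platelet von Willebrand receptor that overlaps a gene on its strand, had -2.16 and 1.08. Pltp, a phospholipid transfer protein gene, had -1.05 and 1.63. The others were Proser2 (-1.11 and 1.27) and Cstdc4 (1.80 and -1.44), named after their values were seen. Adcy6 and Pltp overlap a gene on the opposite strand, and of the 5 only Proser2 is among the genes without overlap or shared sequence. The number was 0 with 5 CPM added or at 4-fold, and 14 with 0.1 CPM added. The erythroid list also lay on opposite sides, with medians of -0.45 for JAK2-617F and 0.67 for MPL515L, and this difference was not tested. Bootstrap intervals over its members were -0.65 to 0.04, which includes 0, and 0.14 to 1.05. The heme synthesis and iron list had medians of -0.03 and -0.19, with 0 of 19 members at least 2-fold higher in either.

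The first pattern weighed was the set of genes far lower in both transduced libraries than in the control. At least 4-fold lower in both were 9.87% (642 of 6504) of genes with an overlap, an unnamed neighbour, or no symbol or GENCODE match. This is 35.1 times the 0.281% among the other genes (18 of 6398). Of the 642, 369 were IDs without a symbol, whose overlap is not known, so the 35.1 does not measure overlap alone. The share was 7.65% for genes with an overlap on the same strand, 4.38% for those with an overlap on the opposite strand alone and 2.04% for those with an unnamed neighbour. The 0.281% argues against lower expression caused by the oncogenes, which would not depend on overlap, for all but a few genes. Depth is argued against by the IDs without a symbol, which took 0.367% of counts in the MPL515L library, near the 0.290% of the shallower JAK2-617F library and far from the 3.42% of the control. A candidate explanation is that reads falling on more than 1 gene were counted in the control only. The settings are not given in the sources used here. The control's 75.6% of even low counts goes with both mates of its pairs being counted only if 1 was not added to every count. Not every class goes with the candidate. Of 168 pseudogenes, 50 were at least 2-fold higher in both and 11 lower in both, against 413 and 1008 of all 12902 genes, which this candidate leaves unexplained.

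The second pattern was the higher mast cell and MHC class II lists and the lower neutrophil maturation list in both transduced libraries. A different counting in the control of reads on overlapping or shared sequence is argued against for the MHC class II and neutrophil maturation lists. On members without either, each of the 3 medians kept its size or more (the smallest was 1.001 times) in both comparisons. The mast cell list kept 21 of its 23 members, so its median could hardly have moved and decides little. Other ways in which the counting of the control could differ were not tested. A lower neutrophil share would raise all other cell types alike, but the medians of the other 10 cell type lists spanned 3.69 log2 units for JAK2-617F and 3.82 for MPL515L. These lists include the mast cell and MHC class II lists, whose medians were known when the test was chosen. Without them, medians ran from -1.82 (eosinophils) to 0.64 (monocytes and macrophages) for JAK2-617F. For MPL515L they ran from -1.51 (eosinophils) to 2.30 (megakaryocytes). With eosinophils left out as well, the JAK2-617F medians ran only from -0.45 (erythroid cells) to 0.64. A lower neutrophil share as the only cause is thus argued against, for JAK2-617F largely by the 8 eosinophil genes. The test cannot exclude that it contributed. A change in which other cells were present, an effect of the oncogenes on differentiation, and any difference in how or for how long the control cells were kept remain open, as untested. The description of the control alone carries a mark of 72 h, whose meaning the labels do not give.

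The third pattern was the higher AP-1 and immediate early list in both transduced libraries. Dusp1 is not a member of this list. It has an overlap and an unnamed neighbour, so the check of counting given next does not cover it. A different counting in the control of reads on overlapping or shared sequence is argued against as the cause. On the 16 of 24 members without either, the median kept 0.995 of its size or more. Other differences in counting were not tested. As to heat or handling stress with a heat shock response, 11 measured heat shock genes had median log2 ratios of -0.554 (JAK2-617F) and -0.720 (MPL515L). Several of these genes, such as Hspa8 and Hsp90aa1, have near copies elsewhere in the genome. The set was not restricted to genes without shared sequence, so the counting of the control may have lowered these ratios. Bag3 (0.17 and 0.13) and Dnajb1 (0.17 and 0.25) were slightly higher in both libraries, and the others were lower. Such stress is therefore argued against only weakly. Open explanations, not tested, are signalling from the oncogenes, handling that induces immediate early genes without heat shock genes, a difference in time behind the 72 h mark of the control, and the mast cells and macrophages whose genes were also higher.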

How the results depend on the processing

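Both gene sets without overlap and the subtraction of 1 from every count were chosen after seeing the data, and the other alternatives before. All results are differences between single libraries, so no test threshold applies. Scaling by library total or by median-of-ratios factors, dropping the floor, leaving out Gm and Rik genes and subtracting 1 from each count kept each count of genes within 1.5 times. Over all alternatives 52 counts stayed within 1.5 times and 36 did not. Of the list medians 25 had another sign than in the main analysis, 20 of them in the gene sets without overlap. In 4 of the 25 the main median lay outside the middle 95% of random lists, and these are given below. Of the others 684 stayed within the bootstrap interval over their members, 15 moved beyond it with the same sign and 5 with another sign. Of single-gene values 1381 stayed within their counting error (inside the interval, or shifted by no more than 0.5 of its width) and 207 did not, and 202 of these had 5 CPM added. Lists with under 3 members left under a setting have no value there. No paired analysis was possible because each group has 1 library.

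In this paragraph counts are given as higher and lower, for JAK2-617F against control, MPL515L against control and JAK2-617F against MPL515L in turn. Less CPM added raises and more CPM added reduces the log2 ratios of low genes by construction. With 0.1 CPM added, 140 genes were higher in JAK2-617F than in MPL515L. With 5 CPM added, 271, 738 and 44 were higher and 297 lower in the last, and 223 were higher in both transduced libraries. A floor of 10 CPM, which leaves fewer genes, gave 315 and 462, 699 and 541, then 48 and 265, with 413 lower in both. The 4-fold threshold gave 115 and 682, 329 and 705, then 11 and 126, with 92 higher and 660 lower in both. Genes without overlap or unnamed neighbour, which are fewer, gave 300 and 171, 716 and 186, then 62 and 334, with 260 higher and 100 lower in both. Leaving out shared sequence too gave 241 and 138, 640 and 148, then 54 and 320, with 214 higher and 76 lower in both. Against the control, though not between the transduced libraries, the numbers of lower genes shrank more than the number of genes did. A candidate cause is the counting of the control. Genes at least 4-fold lower in both were 35.1 times as frequent outside the genes without overlap or unnamed neighbour as among them. Those outside include IDs without a symbol and symbols absent from GENCODE.

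In both restricted gene sets the median of oxidative stress genes for JAK2-617F against MPL515L turned from 0.20 to -0.0111, and that of neutrophil primary granule genes for JAK2-617F against control from -0.35 to 0.0659. The cause was not tested. Adding 5 CPM shrinks log2 ratios by construction, to 1.92 and 3.03 for Dusp1 and 2.45 and 4.21 for Fos in the comparisons of JAK2-617F and MPL515L with the control, and to 7.32 for Mpl in MPL515L against control and -8.09 in JAK2-617F against MPL515L.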

Other observations

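The list medians of glycolysis and hypoxia genes and of p53 targets were higher in the MPL515L library than in the control, with most members within 2-fold. Glycolysis and hypoxia genes had a median log2 ratio of 0.49 against the control, with 6 of 24 at least 2-fold higher and 0 lower. The largest ratios were those of the aldolase Aldoc (3.09), the glucose transporter Slc2a3 (1.83), Ankrd37 (1.77) and the mitophagy receptor Bnip3 (1.77). Ankrd37 and Bnip3 have an opposite-strand overlap and shared sequence. The median was 0.10 for JAK2-617F against the control, with 0 members at 2-fold, and -0.24 for JAK2-617F against MPL515L, with 5 lower. The p53 target list had medians of 0.12, 0.51 and -0.28 in the JAK2-617F, MPL515L and direct comparisons. In the MPL515L library 7 of its 23 members were higher, led by the antiproliferative gene Btg2 (2.30, with an unnamed neighbour) and Perp (1.85), against 3 in the JAK2-617F library. The BCL2 family had medians of 0.05, 0.29 and -0.33, of which the values against the control lie in the middle 95% of random lists, and the proapoptotic genes Bcl2l11 (1.27 and 1.45) and Pmaip1 (1.04 and 1.46), both with an unnamed neighbour, were higher in both transduced libraries. ERK feedback genes had medians of 0.19, 0.64 and -0.20, with 2, 6 and 1 of 13 higher and 0, 0 and 3 lower. On their 4 members without overlap or shared sequence the medians were 0.20, 0.32 and -0.0020. MAP kinases had medians of 0.14, 0.11 and -0.01, in the middle 95% of random lists, with 0, 1 and 1 of 21 higher and 1, 1 and 2 lower. The p38 family member Mapk13 had log2 ratios of -0.44 for JAK2-617F and -1.78 for MPL515L, and Mapk11 had 0.68 and 1.72.

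Cholesterol synthesis genes had medians of 0.34 for JAK2-617F and 0.44 for MPL515L against the control, at percentiles 99.96 and 99.97 among random lists, though none of the 22 reached 2-fold in either. The direct comparison gave -0.11. On the 12 members without overlap or shared sequence the medians against the control were 0.18 and 0.44, beside 0.23 and 0.24 for the 11 such housekeeping genes. The random lists also hold genes with an overlap or shared sequence, and no percentile was computed without them. In the same order, medians were 0.04, -0.10 and 0.17 for the integrated stress and unfolded protein response, -0.03, -0.05 and 0.20 for oxidative stress genes, and -0.03, -0.19 and 0.03 for heme synthesis and iron. The iron exporter Slc40a1 was lower in both transduced libraries, with log2 ratios of -1.20 and -1.84. Small lists of other cells had 5 measured members for B cells (medians 0.33, 1.76 and -0.85), 5 for T and NK cells (0.23, 0.90 and -0.67) and 9 for stromal and endothelial cells (-0.31, -0.44 and 0.38). The interleukin receptor gene Il7r had log2 ratios of 1.10 and 3.63 against the control.

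Some gene classes stood apart from others. Of 35 miRNA genes past the floor, 28 were at least 4-fold lower in both transduced libraries than in the control, as were 102 of 406 lncRNA genes and 369 of 561 IDs without a symbol. Pseudogenes went the other way, with a median log2 ratio of 0.47 for JAK2-617F and 0.51 for MPL515L. At least 2-fold higher in both were 50 of 168 pseudogenes, against 413 of all 12902 genes. Between the transduced libraries, 4-fold differences were found for 1.44% of genes without overlap or unnamed neighbour and for 0.692% of the other genes.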
